A study of Mus musculus with 2 samples.

How the data were processed

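Chromatin from the forebrain of mouse embryos at embryonic day 13.5 was immunoprecipitated with an antibody to H3K27ac and sequenced. Per the labels, there were 2 biological replicates, each with its own tissue sample of pooled male and female embryos, and replicate numbers were taken from the labels. They formed 1 group. Per the labels, the build is mm10, and a control experiment is named as a possible control for both libraries; the control libraries were not analysed here.

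The files were peak lists in narrowPeak format, per the deposited lists of files. The authors called peaks for each replicate alone and for both together, and derived the replicated list from the pooled list and both replicates' lists. The aligner, the peak caller and the rule behind the replicated list are not given in the sources used here. Each deposited peak has a score, which was not used. The ratio used here as fold is the deposited signal value of a peak, read as enrichment over background because the authors' companion tracks are described as fold change over control. The deposited −log10 p and −log10 q are the authors' values, and the lowest −log10 p of a peak was 2.005, in the pooled list. A peak's summit is the deposited position. These values were used to describe, rank and filter peaks within a list, and folds of different lists are given side by side without a test. No list gives reads, so depth is unknown. The lists had 12, 14, 12 and 10 peaks on scaffolds (replicate 1, replicate 2, pooled, replicated), which were left out. No peaks of 1 list overlapped one another.

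Genes were the 21853 protein-coding genes of GENCODE M21 on the 19 autosomes and X and Y of GRCm38, which is the build that mm10 names, with the TSSs of all protein-coding transcripts. A promoter peak overlapped 1 kb either side of a TSS, and a gene's promoter fold is that of its highest such peak. Such a peak need not cover the TSS and counts for every gene in range, so it can be that of a neighbouring gene. All other peaks are called distal, and a distal peak was given to the nearest TSS of its summit within 100 kb. Exonic, intronic and outside positions are those of a peak's summit and refer to protein-coding genes. Domains were peaks joined over gaps of at most 12.5 kb, ranked by covered length.

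Overlap of peak lists was set beside 100 random shifts along each chromosome. Lists of genes were compared with all other protein-coding genes by Fisher's exact test, two-sided, for promoter peaks and for the 1000 widest domains. Mean distal peaks were compared with 10000 random lists of the same size drawn within 20 bins of the distance between neighbouring TSSs. Each family was adjusted over 21 lists by the Benjamini-Hochberg method, with a threshold of 0.05. The lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. They comprise 18 lists of known genes and 3 sets defined by symbol, and the set of symbols starting with Rpl or Rps also takes in some kinases and pseudogenes. Per list, the members named are up to 4 with the highest fold and up to 4 without a peak, in list order, and those with a promoter peak in 1 replicate's list only where they are 5 or fewer. The 20 largest domains and the 10 distal peaks of highest fold are also named. Other genes are named only where stated.

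Alternatives changed the overlap that counts (50% of either peak), the threshold on peaks (−log10 q of at least 2 or 5), the peak list, the promoter window (0.5 or 2.5 kb), the TSS set, the background (random genes matched on the ratio of observed to expected CpG around the 5′-most TSS), the reach (50 or 250 kb), the joining gap (5 kb or none) and the number and ranking of domains. Leaving out a replicate means using the other replicate's own peaks. Keeping 1 member of a list per 200 kb was added after the data were seen.

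Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. The functions were tested on simulated data. Overlaps and joined domains of 5000 simulated peaks equalled those of bedtools 2.31.1. With lists of 18 genes among 21853, the promoter test called 98.3% of lists simulated with nearly all or nearly no members marked and 1.67% of unchanged lists. The distal test called 30% of lists whose counts were doubled with 2 added, and 0.833% of unchanged lists, so a list that did not pass it can still differ.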

Results

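Acetylation of lysine 27 of histone H3 (H3K27ac), a mark of active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing in the forebrain of mouse embryos at embryonic day 13.5. The series held 1 group of 2 biological replicates, each from its own tissue pool of male and female embryos of a C57BL/6 substrain. The forebrain at this age comprises the telencephalon, which forms cortex and basal ganglia, and the diencephalon, which forms thalamus and hypothalamus. No other tissue, age or treatment was part of the series, so the comparisons are those between the replicates, between promoters and the rest of the genome, and between lists of genes. The deposited files listed 90396 peaks for replicate 1, 114783 for replicate 2, 125932 for both replicates together (the pooled list) and 53104 in a list that the submitters named replicated peaks. The files gave no read counts, so the depth of each library is unknown and no counting interval could be given. Positions are in mm10, and a fold is the enrichment that the authors deposited for a peak in its own list.

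The first comparison asked how far the replicates shared their acetylated regions. Of the 90384 peaks of replicate 1 on the chromosomes, 54371 (60.2%) overlapped a peak of replicate 2 by at least 1 base, and the mean after 100 random shifts of the peaks of replicate 2 was 3.95% (highest 4.52%). In the other direction 54605 of 114769 peaks (47.6%) overlapped, against 3.16% after shifts. Sharing followed the strength of a peak. Among peaks of −log10 q below 2, 33.5% of those of replicate 1 and 20.0% of those of replicate 2 were shared. For −log10 q from 10 to 20 the shares were 99.2% and 99.0%. When both lists were limited to −log10 q of at least 5, the shares were 75.2% and 73.5%. Replicate 2 had more peaks than replicate 1, by 1.27 times in total and by 1.025 times at −log10 q of at least 5 (31480 against 30715). Each of the 54371 overlapping peaks of replicate 1 was paired with the overlapping peak of replicate 2 of highest fold. A peak of replicate 2 could be paired more than once. Over these pairs, Spearman's rho of the folds was 0.633 and Pearson's r of log2 fold was 0.757. These are correlations across peaks, which are not independent replicates, and they carry no p-value.

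**Figure D1:**
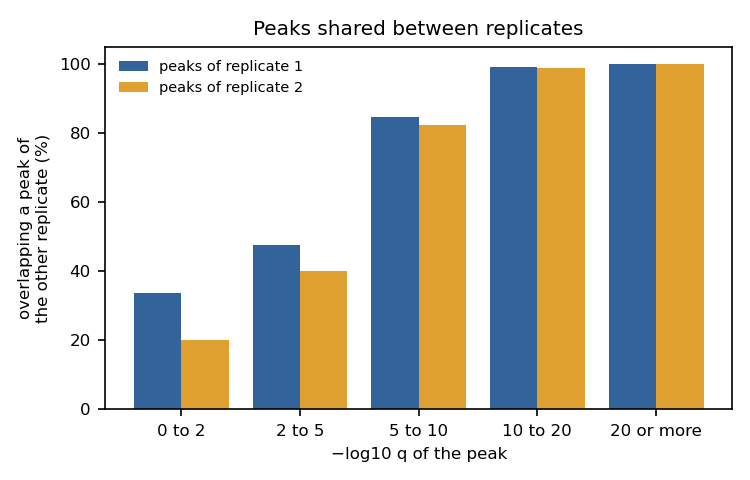
Share of the peaks of each replicate (vertical axis, %) that overlapped a peak of the other replicate by at least 1 base, by the peak's −log10 q in its own list (horizontal axis). Bars are single shares for replicate 1 and replicate 2, and rise from 33.5% and 20.0% below 2 to 99.2% and 99.0% between 10 and 20.

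The replicated list was examined next, since the comparisons of genes rest on it. All 53104 of its peaks were in the pooled list with the same positions and values. On the chromosomes 53094 peaks remained, covering 49.6 Mb, with a median width of 629 bases. Of these, 48512 (91.4%) overlapped a peak of replicate 1, 49605 (93.4%) a peak of replicate 2 and 45210 (85.2%) a peak of both. A further 3302 overlapped a peak of replicate 1 only, 4395 of replicate 2 only and 187 of neither. A replicated promoter peak at a gene therefore did not always come with a peak in both replicates' own lists. Of the 72826 pooled peaks outside the replicated list, 645 overlapped a peak of both replicates by at least 1 base. By 50% of either peak, 0 did.

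Promoters of protein-coding genes held a large part of the acetylated regions. Of the replicated peaks, 13574 (25.6%) lay within 1 kb of a transcription start site (TSS) of a protein-coding gene, against 3.63% after random shifts (3.32 to 4.08%). The share was 19.5% among the peaks of replicate 1, 16.9% among those of replicate 2 and 15.4% in the pooled list. By summit, introns held 40.9% (34.9% after shifts), exons 3.96% (3.05%) and sequence outside protein-coding genes 29.6% (58.4%). Median fold was 7.20 for promoter peaks and 3.99 for all other (distal) peaks of the replicated list, a ratio of 1.80. In the replicates' own lists the ratio was 1.47 in replicate 1 and 1.46 in replicate 2, so both showed the same direction. Promoter peaks were also wider, with a median of 869 against 575 bases. Any overlap with the window makes a promoter peak, which favours wide peaks, so the definition can add to this difference. Widths were not compared with shifted peaks. Distal summits lay a median of 36.5 kb from the nearest TSS, and 29978 (75.9%) were within 100 kb. Of the 21853 protein-coding genes, 10914 (49.9%) had a replicated promoter peak. In the replicates' own lists 10794 genes had a promoter peak in both, 551 (2.52%) in replicate 1 only and 1115 (5.10%) in replicate 2 only.

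Transcription factor genes of the telencephalon were nearly all acetylated at their promoters. All 18 genes of the dorsal list, which pattern the cortex and specify its excitatory neurons, had a replicated promoter peak, against 49.9% of other genes (Fisher's exact test, two-sided, adjusted p = 1.11e-05 over 21 lists). The highest folds were at Foxg1, a regulator of telencephalic identity (fold 55.2 in the replicated list, 45.2 and 49.0 in replicates 1 and 2), Bcl11b, a factor of deep-layer and striatal neurons (37.0), Lhx2 (31.8) and Emx2 (25.4), both regulators of cortical patterning. The replicates' own folds at Emx2 were 22.0 and 11.9. In replicate 2 Fezf2 (22.6), Neurog2 (21.8) and Tbr1 (21.8), among others, were above Emx2. In Fisher's exact test the ventral list, of genes that act in the ganglionic eminences where inhibitory neurons arise, had 16 of 18 members with a peak (88.9%, adjusted p = 0.00117). Nr2f2 (fold 33.0), Dlx6 (29.2), Dlx1 (28.4) and Meis2 (24.4) were highest. Gsx1 and Gsx2, regulators of ventral progenitors, had none, although replicate 1 alone listed a peak at Gsx2 (fold 3.54). Against random genes of the same promoter CpG content, 75.8% of which had a peak, the ventral list did not pass (n = 18 genes, adjusted p = 0.341; 0.000325 to 0.341 over the alternatives).

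**Figure D2:**
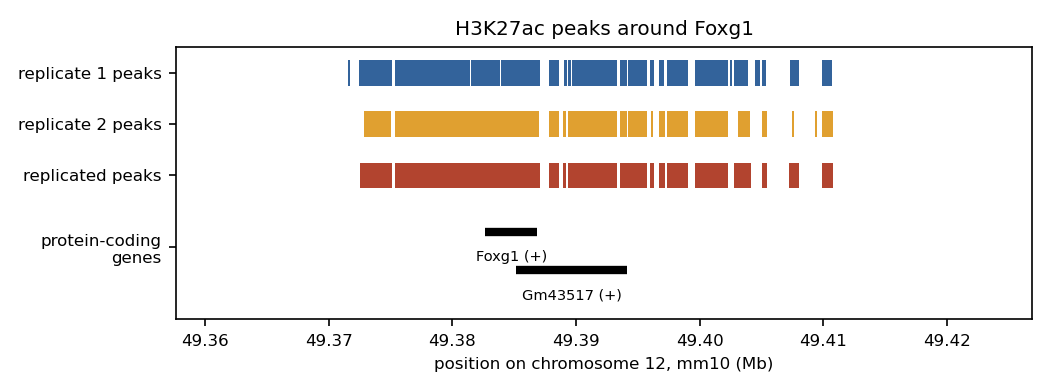
Peaks of replicate 1, of replicate 2 and of the replicated list (boxes, to scale) around Foxg1 on chromosome 12 of mm10 (horizontal axis, Mb), with protein-coding genes as black bars and their strand in brackets. The replicated peak from 49375340 to 49387093 spans Foxg1, and another from 49399598 to 49402280 lies downstream of Gm43517.

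Progenitor and pan-neuronal genes all had promoter peaks, and bulk tissue cannot tell whether the same cells carried both. All 18 neural progenitor genes had a replicated promoter peak (adjusted p = 1.11e-05, Fisher's exact test), led by the stem cell factor Sox2 (fold 52.1), the RNA-binding protein gene Msi1 (47.2), and the POU factors Pou3f3 (44.2) and Pou3f2 (42.5). The 2 replicates gave 45.1 and 44.5 at Sox2, and 31.8 and 52.3 at Msi1. All 18 pan-neuronal genes had one as well (Fisher's exact test, adjusted p = 1.11e-05). Their highest folds were at Myt1l, a transcription factor of neurons (34.9), the tubulin gene Tubb3 (25.6), the microtubule-associated protein gene Map2 (23.4) and the RNA-binding protein gene Elavl4 (20.9). Genes of mature neurons and activity were mixed. A peak was present at 12 of 18, which did not pass Fisher's exact test (66.7% against 49.9%, adjusted p = 0.175), but with the pooled list the share was 83.3% (adjusted p = 0.0365; 0.0365 to 0.536 over the alternatives). The inhibitory transmitter genes Gad2 (fold 23.6), Slc32a1 (18.7) and Gad1 (18.1) led, followed by the kinase gene Camk2a (13.3). The replicates' own folds at Camk2a were 15.7 and 7.31. Egr4, Nptx2, Grin2a and Pvalb were among those without. Promoter peaks were listed in replicate 1 only at Nptx2 and Sst, and in replicate 2 only at Grin2a and Slc17a7.

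Transcription factors of the diencephalon and hypothalamus had a peak at 8 of 16 genes, close to the share of other genes (50% against 49.9%, Fisher's exact test, adjusted p = 1). Tcf7l2, a thalamic factor (fold 15.9), Vax1 (11.2), Lhx9 (10.97) and Fezf1 (6.59) were highest, and Sim1, Nkx2-2, Nkx2-4 and Rax were among those without. Otp, Nkx2-2 and Nkx2-4 had a promoter peak in replicate 2 only, and Dbx1 in replicate 1 only. Random genes of the same promoter CpG content had a peak in 80.0%, and against these the list was below (n = 16 genes, adjusted p = 0.0171; 0.0171 to 1 over the alternatives). The share depended on the peak list and window, with 37.5% within 0.5 kb, 62.5% in replicate 2 and 81.25% in the pooled list, where it did not pass (exact test, adjusted p = 0.0548). Genes of regions behind the forebrain were seldom acetylated. The midbrain and hindbrain factors had a promoter peak at 1 of 18 genes (5.56%, Fisher's exact test, adjusted p = 0.000378), Mafb (fold 14.2), and none at En1, En2, Pax2 or Pax5. Replicate 2 alone listed a peak at Gata2 and Tal1, so its share was 16.7%. None of the 39 Hox genes, which pattern the body behind the midbrain, had a promoter peak in the replicated list or in either replicate (Fisher's exact test, adjusted p = 1.85e-11), Hoxa1, Hoxa2, Hoxa3 and Hoxa4 included. Hox genes lie in 4 clusters and are not independent. With 1 member kept per 200 kb the share was still 0, and 4 genes are too few to pass the exact test at any outcome (adjusted p = 0.164; 5.96e-14 to 0.164 over the alternatives).

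Glial genes had few promoter peaks at this age. In the astrocyte and oligodendrocyte list 2 of 18 members had one (11.1%, Fisher's exact test, adjusted p = 0.00196), the lineage factor Olig2 (fold 3.46) and the myelin gene Cnp (3.19). The peak at Olig2 was listed in replicate 2 and not in replicate 1. Gfap, Aqp4, Aldh1l1 and S100b had none. Peaks were listed in 1 replicate only at Mbp and Ermn (replicate 1) and at Mobp and Olig2 (replicate 2). Sox10 had one in both replicates (folds 2.603 and 3.283) and none in the replicated list. With either replicate's own peaks the share was 22.2% (exact test, adjusted p = 0.0199 in replicate 1 and 0.0102 in replicate 2), and in the pooled list 27.8%.

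Markers of other cell types that a forebrain dissection can contain were acetylated at a minority of promoters, with low folds at most. The endothelial and pericyte list had 3 of 18 (16.7%, exact test, adjusted p = 0.00986), Vtn (fold 10.04), Egfl7 (3.99) and Kdr (3.16), and none at Pecam1, Cdh5, Flt1 or Tie1. The peak counted for Vtn ended at 78498589, before its TSS at 78499120, and can belong to a neighbouring gene. Peaks were in replicate 1 only at Kdr and Esam and in replicate 2 only at Cdh5 and Emcn. The microglia and macrophage list also had 3 of 18 (16.7%, exact test, adjusted p = 0.00986), Aif1 (3.47), Cd68 (3.47) and Tmem119 (2.91), and none at Csf1r, Cx3cr1, Spi1 or Itgam. Replicate 1 alone listed a peak at Csf1r, and replicate 2 alone at Spi1, Trem2, C1qb and Irf8. With the peaks of replicate 2 the share of the microglia list was 38.9% (exact test, adjusted p = 0.249), and against genes of the same CpG content 16.7% stood beside 20.9% (adjusted p = 0.957; 2.54e-05 to 0.957 over the alternatives). Blood genes had a peak at 4 of 18 (22.2%, exact test, adjusted p = 0.0381), led by the transferrin receptor gene Tfrc (13.4), which many dividing cells use, then Ank1 (5.21), Nfe2 (3.99) and Klf1 (2.87), the last listed in replicate 2 and not in replicate 1. The erythroid factor gene Gata1 and the globin genes Hba-a1, Hba-a2 and Hbb-bt had none. The globin genes have near-identical copies within the alpha and within the beta family, so their values are uncertain. The blood list stood at the share of genes of the same CpG content, 22.2% against 22.3% (n = 18 genes, adjusted p = 1; 0.00552 to 1 over the alternatives).

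The meninges and mesenchyme list (5 of 18, 27.8%) and the choroid plexus and ependyma list (5 of 18, 27.8%) did not pass Fisher's exact test (adjusted p = 0.106 for each). Crabp2 (fold 4.71), Foxd1 (4.51), Prrx1 (4.40) and Foxc1 (4.34) led the first, and the collagen genes Col1a1, Col1a2 and Col3a1 and the proteoglycan gene Lum had no peak. Otx2 (6.59), Foxj1 (6.25), Rspo3 (4.63) and Bmp7 (3.97) led the second, and the choroid plexus transport protein gene Ttr, and Msx1, Msx2 and Wnt3a had none. Both lists were below genes of the same CpG content (n = 18 genes each, adjusted p = 0.00875 and 0.00672). Their ranges over the alternatives were 0.00875 to 0.172 and 0.00672 to 0.639. Peaks in 1 replicate only were at Col1a2, Wnt2b and Rspo2 (replicate 1) and at Tbx18 and Rspo3 (replicate 2). Folr1 had one in both replicates and none in the replicated list, and the choroid plexus list reached 50% in the pooled list. Tissues outside the head were below. Liver genes had a peak at 2 of 19 (10.5%, exact test, adjusted p = 0.00117), Apoh (10.4) and Foxa3 (4.50), and none at Alb, Afp, Apoa1 or Apoa2. Heart and muscle genes had one at 2 of 20 (10%, exact test, adjusted p = 0.000764), Myh7 (15.3) and Nppa (3.28), and none at Nkx2-5, Gata4, Gata6 or Tbx5. The peaks counted for Foxa3 and Myh7 covered no TSS of these genes. In 1 replicate only were Foxa3 (replicate 2) and Tnni3 and Mymk (replicate 1), and the share of heart and muscle genes was 20% in replicate 1. Of the 19 liver genes, replicate 1 listed a peak at 1, Apoh.

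Genes of general cell functions were mostly acetylated. The cell cycle list had 18 of 20 members with a peak (90%, exact test, adjusted p = 0.000455), with Cdc20 (fold 12.8), Ccna2 (11.1), Aurkb (10.1) and Mcm6 (10.02) highest and none at Mcm3 and Bub1. In replicate 1 the highest fold of this list was at Aurka (10.9), whose fold in replicate 2 was 5.16. The replicated peak at Ccne1 (fold 4.16) was listed in replicate 1 and not in replicate 2. Genes of the same CpG content had one in 78.1%, and the list did not pass against these (n = 20 genes, adjusted p = 0.341; 0.00027 to 0.341 over the alternatives). The housekeeping list also had 18 of 20 (90%, exact test, adjusted p = 0.000455), with Actb (54.3), Ywhaz (45.5), Tubb5 (38.7) and Vcp (35.6) highest and none at B2m and Gusb. This order is that of the replicated list. In replicate 1 the folds of Tubb5 (22.3) and Vcp (23.2) were below those of Polr2a (26.3) and Eef1a1 (24.8). Replicate 2 alone listed a peak at B2m, and replicate 1 alone at Gusb. Of the 102 genes whose symbols start with Rpl or Rps, 89 had a peak (87.3%, exact test, adjusted p = 1.41e-14). Rpl7 (32.2), Rpl32 (23.5) and Rpl29 (21.5) were highest, with Rps6ka5 (21.5), which encodes a kinase and not a ribosomal protein. Rpl10-ps3, Rpl10l, Rpl22 and Rpl36-ps4 were among those without. Replicate 2 alone listed a peak at Rpl22, and replicate 1 alone at Rps6kl1, another kinase gene. Chemosensory receptor genes had almost no promoter peaks. None of 1134 olfactory receptor genes and 1 of 331 vomeronasal receptor genes, Vmn1r4 (fold 5.78), had a replicated promoter peak (0.302%, exact test, adjusted p = 1.39e-97 for the latter). Replicate 1 alone listed a peak at 2 olfactory receptor genes, and replicate 2 alone at 5. Both families lie in clusters of similar copies, so members are not independent. Fisher's exact test over genes describes these 2 libraries, and does not measure variation between embryos.

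**Figure D3:**
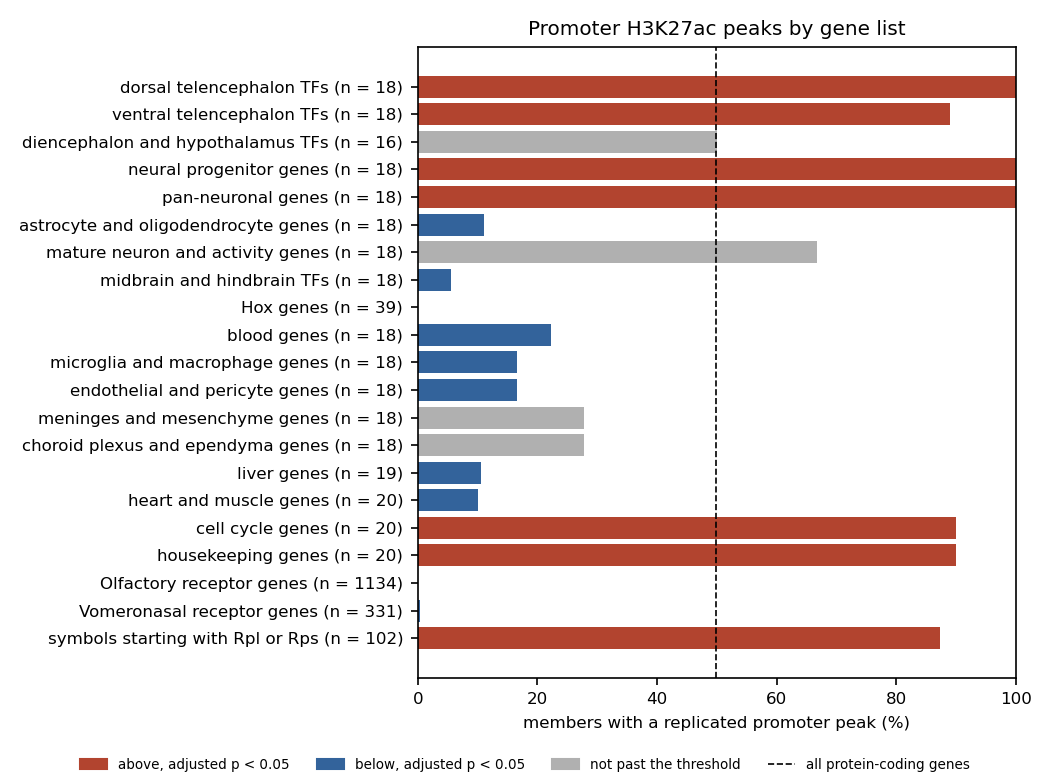
Share of the members of each of 21 gene lists (horizontal axis, %) with a replicated peak within 1 kb of a TSS, with the number of genes in brackets. Bars are red above and blue below other genes with an adjusted p under 0.05 (Fisher's exact test) and grey otherwise. The dashed line is the share of all protein-coding genes, 49.9%, and the dorsal, progenitor and pan-neuronal lists reach 100% while the Hox and olfactory receptor lists stand at 0.

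Distal peaks were numerous near the telencephalic, progenitor and neuronal genes. Dorsal telencephalon factors had a mean of 9.61 distal peaks whose nearest TSS within 100 kb was theirs, against 2.97 for 10000 random lists of genes with similar spacing to their neighbours (n = 18 genes, percentile 99.96, adjusted p = 0.007). Pan-neuronal genes (n = 18) had 10 against 2.9 (adjusted p = 0.00945), progenitor genes 8.44 against 2.61 (adjusted p = 0.0151) and ventral factors 7.33 against 2.48 (adjusted p = 0.0364). The means depended on the peak list. With the peaks of replicate 1 and of replicate 2 they were 16.6 and 17.5 for the dorsal list, 19.3 and 20.9 for the pan-neuronal, 15.3 and 17.6 for the progenitor, and 13.9 and 14.8 for the ventral list. All 4 lists passed with either (n = 18 genes each, highest adjusted p = 0.0492, for the ventral list with replicate 2). A few genes raised some of the means, and medians were 6.5 in the dorsal, 5.5 in the pan-neuronal, 9 in the progenitor and 5.5 in the ventral list. In the replicated list Bcl11b had 44 such peaks and Emx1 19, Rbfox3 43 and Myt1l 28, Sox2 20 and Id4 17, Meis2 22 and Nr2f2 20. Foxg1 and Eomes had 1 each. The gene Gm43517, whose TSS lies 3' of that of Foxg1, was the nearest to 15, so distal peaks 3' of Foxg1 counted for Gm43517. No such peak was nearest to Tubb3, Syt1, Ina, Zic1, Gsx1 or Dlx5. Olfactory (n = 1134, 0.0194 against 0.471) and vomeronasal receptor genes (0.00604 against 1.23) were below (adjusted p = 0.0021 for both, from the smallest p that 10000 random lists can give). The other 15 lists did not pass, among them mature neuron genes (n = 18, 3.11 against 1.99, adjusted p = 0.418), diencephalon factors (4.81 against 2.73, adjusted p = 0.28) and Hox genes (0.103 against 0.401, adjusted p = 0.171). Astrocyte and oligodendrocyte genes had 1.67 against 1.48 (n = 18, adjusted p = 0.81). Hox genes (n = 39) were below random lists with the peaks of replicate 2 (adjusted p = 0.0147), with those of replicate 1 (0.0174) and without matching (0.0007; 0.0007 to 0.17 over the alternatives). Diencephalon factors (n = 16) were above without matching (adjusted p = 0.0457; 0.0457 to 0.467). Meninges genes (n = 18) were below with a reach of 250 kb (adjusted p = 0.0378; 0.0378 to 0.69), and liver genes (n = 19) with 50 kb (adjusted p = 0.0474; 0.0474 to 0.51). The nearest gene is a statement of position, and the gene a distal peak acts on was not measured.

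**Figure D4:**
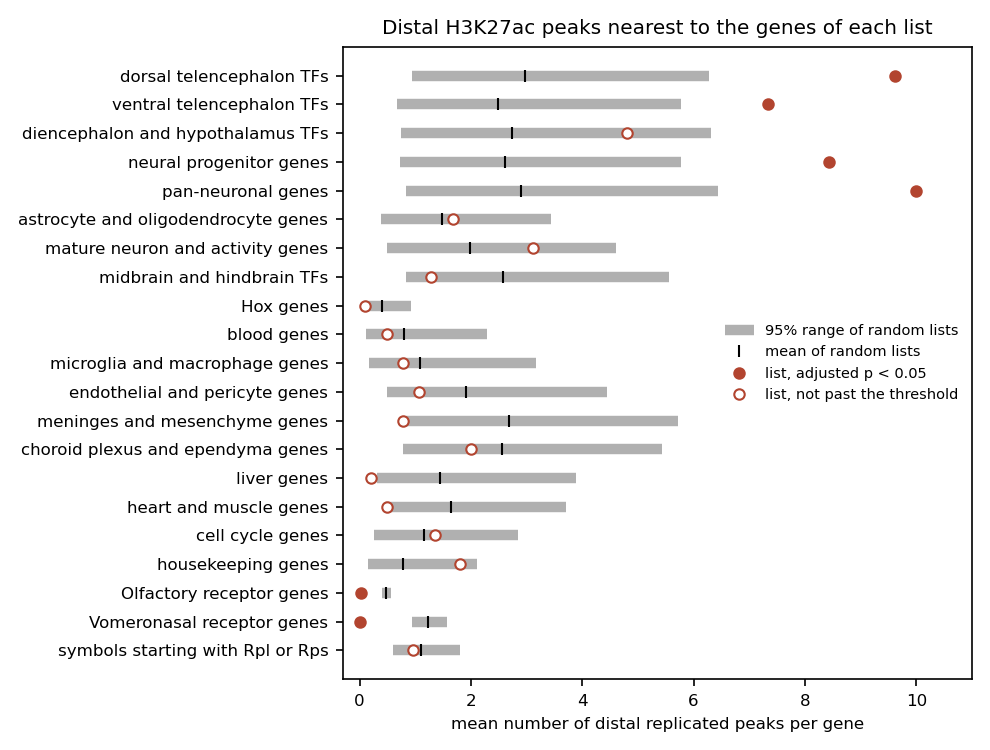
Mean number of distal replicated peaks per gene in each list (circles, horizontal axis), filled where the adjusted p was under 0.05, with the mean (tick) and the 95% range (grey bar) of 10000 random lists matched on gene spacing. The dorsal (9.61), pan-neuronal (10), progenitor (8.44) and ventral (7.33) lists lie above their ranges.

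Of the 10 distal peaks with the highest fold, 7 had the TSS of a long non-coding RNA gene within 1 kb, against 1482 of all 39520 (3.75%). The 10 were 1.278 to 46.49 kb wide, and the median distal peak 575 bases. A wide peak is likelier to have a TSS within 1 kb, and the shares were not matched on width. The highest, with fold 68.2 (45.5 and 58.7 in replicates 1 and 2), spanned 21.1 kb on chromosome 13 from 83713489 to 83734569. The TSSs of the long non-coding RNA genes C130071C03Rik and Gm26803 lay there, and its summit was 78.1 kb from the nearest protein-coding TSS, of Mef2c. A peak on chromosome 5 (115489113 to 115490390, fold 60.1) lay 5.40 kb from Sirt4, and one on chromosome 7 (73556605 to 73558619, 59.7) within 1 kb of the TSS of 1810026B05Rik, near Chd2. The peak on chromosome 12 (49399598 to 49402280, 57.6) lay near Foxg1, with Gm43517 as the nearest gene. Next were 2 peaks on chromosome 2, from 30715837 to 30726679 at Gm14488 (55.1) and from 30689961 to 30696285 (51.6), and a peak on chromosome 14 from 25377057 to 25380278 at Gm26660 near Zmiz1 (51.8). The last 3 were on chromosome 11 (96871383 to 96879921, Gm11523, 49.95), on chromosome 3 (88196487 to 88242981, 49.9) and on chromosome 19 (5799662 to 5805825, 49.8), the last within 1 kb of the TSS of Malat1, an abundant nuclear RNA. The summits of all 10 lay outside protein-coding genes, and all 10 had a peak in both replicates.

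Long acetylated domains lay at most of the telencephalic transcription factor genes and progenitor genes. Peaks that lay close to one another were joined into 22598 domains, and the 1000 with the largest covered length (7.52 kb or more) held a TSS of 1228 genes (5.62%). Ventral factors had 14 of 18 members there (77.8%, adjusted p = 7.58e-14), progenitor genes 13 of 18 (72.2%, adjusted p = 2.41e-12) and dorsal factors 11 of 18 (61.1%, adjusted p = 1.96e-09; Fisher's exact test, two-sided). Pan-neuronal genes had 3 of 18 (16.7%, exact test, adjusted p = 0.161). The difference between these lists was not tested. In the ventral list Dlx1 and Dlx2 shared the domain of rank 72, and Dlx5 and Dlx6 that of rank 71, so these members are not independent. Keeping 1 member per 200 kb was not applied to domains. With the 2000 widest domains the pan-neuronal list was above other genes (44.4%, exact test, adjusted p = 0.000274; 0.000118 to 0.327 over the alternatives). Housekeeping genes (5 of 20, adjusted p = 0.0148), mature neuron genes (4 of 18, adjusted p = 0.0423) and genes starting with Rpl or Rps (13 of 102, adjusted p = 0.0221) also passed Fisher's exact test. The mature neuron list did not pass the exact test with either replicate's own peaks (adjusted p = 0.134 and 0.078), and the Rpl and Rps list not with those of replicate 1 (adjusted p = 0.078). With the 500 widest domains no housekeeping gene was included (exact test, adjusted p = 1), and without joining no Rpl or Rps gene (adjusted p = 0.593). Over the alternatives of this exact test the adjusted p ranged from 0.00167 to 0.285 for the mature neuron list, from 0.000112 to 1 for the housekeeping list and from 0.000135 to 0.595 for the Rpl and Rps list. Olfactory (adjusted p = 2.43e-28) and vomeronasal receptor genes (adjusted p = 3.7e-08) were below, with no member there (Fisher's exact test). The other 13 lists did not pass, although diencephalon factors did with a joining gap of 5 kb (18.75%, exact test, adjusted p = 0.0334; 0.0334 to 0.835 over the alternatives).

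The domain of largest covered length spanned 352.4 kb on chromosome 8 (120250839 to 120603219) with 112 peaks covering 170.2 kb, and held TSSs of Gse1 and Gins2. The second, on chromosome 11 (88328686 to 88730168, 156.8 kb covered), held Msi2, an RNA-binding protein gene of neural progenitors. Others of the 20 largest held Cstad with 4 other genes (100.8 kb), Zmiz1 (88.9 kb), Nfix with G430095P16Rik and 3 others (86.3 kb), the imprinted gene Nnat with Blcap and Src (79.4 kb), Rhcg (72.7 kb), the corepressor gene Ncor2 (71.9 kb), Tcf4 (64.4 kb), Pbx1 (60.1 kb), Prdm16 (60.1 kb), Tcf20 (55.8 kb), Bcl11b (55.7 kb) and Meis2 (55.2 kb). The rest held Midn in a region of 12 genes (53.2 kb), Trak1 (52.8 kb), Stra6 (52.1 kb), Gm26897 (48.8 kb) and Fyn (46.6 kb). The domain at rank 19, on chromosome 3 from 88192558 to 88243742, held no protein-coding TSS and had Rhbg as its nearest gene. Tcf4, Pbx1, Prdm16, Bcl11b and Meis2 encode transcription factors that act in forebrain progenitors or neurons.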

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

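Signal outside the main measurement was looked for in the peaks that the comparisons of genes did not use. The pooled list held 3250 peaks of −log10 q of at least 5 that were not in the replicated list. Of these, 1340 overlapped a peak of replicate 1 only, 1680 of replicate 2 only, 40 of both and 190 of neither. Their highest fold was 5.55 and their median 3.64, and 358 (11.02%) were at promoters. For 109 genes the only such promoter peak was among them, including, from the fixed lists, C1qb, Grin2a, Mbp and Sox10, which were named after their values were seen. The second set was 10 replicated peaks on scaffolds outside the chromosomes, of which 1 had a fold of 40.6.

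The tests of peak numbers, and those of CpG content on 4 single lists, were chosen after the results were seen. Replicate 2 had 1.27 times as many peaks as replicate 1. Strongly acetylated regions of replicate 2 alone are not the source, since 0.474% of its peaks of −log10 q of at least 10 (75 of 15833) had no overlapping peak of replicate 1. At −log10 q of at least 5 the ratio was 1.025, which is consistent with an excess of weak peaks near the calling threshold. Depth and background are open as a reason for these, since no reads were used, and no biological explanation was tested.

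Promoter peaks differed from other genes in 17 lists, 7 above and 10 below. Promoters rich in CpG are acetylated in many tissues, so CpG content could set these differences. Against random genes of the same promoter CpG content 5 of the 7 lists stayed above and 8 of the 10 stayed below, which argues against CpG content as the whole cause for those lists. It stays open for the ventral telencephalon and cell cycle lists (n = 18 and n = 20 genes, adjusted p = 0.341 for both) and for the blood and microglia lists (n = 18 genes each, lower adjusted p = 0.957). There the difference from matched genes shrank, from 88.9% against 49.9% to 88.9% against 75.8% in the ventral list. With 1 member per 200 kb, 15 of the 17 lists still passed. The dorsal, progenitor, midbrain and hindbrain, endothelial, cell cycle and housekeeping lists had no members that close. They lost none, so the thinning could not change their counts. The olfactory list, cut from 1134 to 173 members, and the vomeronasal list, cut from 331 to 110, still passed. Neighbouring genes counted as independent thus do not account for most calls. The blood list did not pass (4 of 13 members with a peak). For the Hox list the test decides nothing, since its 4 remaining members, none with a peak, were too few to pass.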

How the results depend on the processing

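Among the alternatives only 1 member per 200 kb was chosen after seeing the data. The number of gene lists past the threshold stayed within 1.5 times for promoter peaks (17; 15 to 19) and distal peaks (6; 6 to 8) under all alternatives, and for wide domains (8; 6 to 10) under all but the 500 widest domains, which gave 5. Of single lists' values, 170 of 189 for promoter peaks, 115 of 126 for distal peaks and 125 of 147 for wide domains kept their direction and side of the threshold. The direction changed for 4, 5 and 11. In 3 of these 20 the main value or the alternative passed: diencephalon promoters against genes of the same CpG content (50%, n = 16, adjusted p = 0.0171), housekeeping genes in the 500 widest domains (0%, exact test, adjusted p = 1) and Rpl and Rps genes without joining (0%, exact test, adjusted p = 0.593). In the other 17 neither passed. Diencephalon promoters had 37.5% with 0.5 kb, 50% with 2.5 kb and 50 to 62.5% without either replicate. Mean distal peaks were 1.667 for astrocyte and oligodendrocyte and 1.569 for Rpl and Rps genes with 250 kb, 2.049 to 2.794 for the latter without either replicate, and 2 for choroid plexus and 1.35 for cell cycle genes without matching. In wide domains lay 0% of diencephalon factors and 11.11% of microglia genes ranked by fold times width. Microglia genes had 5.556% with a gap of 5 kb, 11.11% in the 2000 widest and 11.11% without either replicate. Choroid plexus genes had 11.11% with 5 kb and in the 2000 widest, and meninges genes 5.556% in the 500 widest. At −log10 q of at least 5, overlap was 75.2% of replicate 1 and 73.5% of replicate 2, and rho 0.721. For replicate 2 overlap was also 56.5% at −log10 q of at least 2 and 61.7% with equal numbers of peaks of highest fold. Rho was 0.665 with −log10 p and 0.664 with overlap of 50%. Replicated peaks with both replicates were 84.6% with overlap of 50% and 69.9% at −log10 q of at least 2. The promoter share was 29.6% with 2.5 kb, 21.5% with 1 TSS per gene, 15.4% in the pooled list, 30.1% at −log10 q of at least 5 and 16.9 to 19.5% without either replicate. The promoter to distal ratio was 2.70 for −log10 p, 1.51 for width, 1.91 with 0.5 kb, 1.61 with 2.5 kb and 1.46 to 1.47 without either replicate. Merging overlapping peaks changed nothing since none overlapped. Stricter thresholds leave fewer weak peaks; for the other changes the cause was not tested. Depth is unknown, so missing weak peaks cannot be told from absent acetylation. No paired analysis was possible because the series has 1 group.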

Other observations

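Many microRNA genes of neural tissue lay in replicated peaks. All 3 copies of Mir9, a microRNA of neural progenitors, were in a replicated peak, and their domains ranked 19 (Mir9-1, chromosome 3), 45 (Mir9-2, chromosome 13) and 7 (Mir9-3, chromosome 7) by covered length. The replicated peak at Mir9-1 was 46.5 kb wide, with fold 49.9. It lies in the domain without a protein-coding TSS near Rhbg, and Mir9-3 lies in the domain of Rhcg. Mir9 was noticed from these positions and is left out of the test. A list of 12 other neural microRNA genes and a list of 14 of other tissues were written before their positions were compared with peaks. In the second list Mir10a and Mir196a-1 lie among the Hoxb genes and Mir208a within Myh6. Those genes had no promoter peak, so these members were not independent of the results for gene lists. Of the neural list 9 were in a replicated peak, among them Mir124a-1 (fold 47.0), Mir125b-1 (33.9), Mir124a-3 (33.3) and Mir124a-2 (29.7), and 7 were in the 1000 widest domains. Of these 9, Mir7-2 lay in a peak of replicate 1 and in none of replicate 2. Mir128-1, Mir219a-2 and Mir219b were not in a peak. None of the 14 other genes was, Mir122 of liver, Mir1a-1 of muscle and Mir223 of myeloid cells included (Fisher's exact test, two-sided, p = 7.04e-05). Some of these genes are neighbours, and counted as loci the values were 9 of 11 and 0 of 9 (exact p = 0.000333). Of all 2202 microRNA genes, 226 were in a replicated peak. The result is consistent with the hypothesis that neural microRNA genes are acetylated in this tissue, and microRNA levels were not measured.

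A second hypothesis was that binding sites of neural transcription factors are more frequent around the summits of distal peaks than in other sequence of the same GC content. It was tested on 6 hexamers fixed beforehand, over 39509 windows of 500 bases with repeats left out. The rule set, that most of the 6 rank in the top 5% of 2080 hexamers, was not met, since only 1 did. A rank among hexamers cannot decide whether the sites were more frequent. The ratios of all 6 were above 1, but such ratios were common, since CACGTG with 0.999 ranked only 1157. The hexamer that did was TAATTA, a core site of homeodomain factors, which was 2.08 times as frequent as in the matched windows and ranked 1. GC content was matched before repeats were left out, and with repeats kept the ratio of TAATTA was 1.90 and its rank 3. The E-box CAGCTG had a ratio of 1.29 (rank 274), ATGCAA of POU factors 1.16 (rank 539) and TTGGCA of NFI factors 1.13 (rank 641). For the E-box CAGATG the ratio was 1.12 (rank 682), and for ACAATG of SOX factors 1.06 (rank 942). Of 5 hexamers of other factors, CGGAAG of ETS factors had 1.19, CACGTG of MYC 0.999, GGAATG of TEAD 0.957, GATAAG of GATA 0.888 and TGAGTC of AP-1 0.868. With repeats left out the neural ratios were thus above 1 and 4 of the 5 others below, differences that were not tested. With repeats kept the neural ratios were still above 1, but so were CACGTG (1.144) and CGGAAG (1.013). CACGTG then stood above ATGCAA (1.126), CAGATG (1.122) and ACAATG (1.12). Repeat sequence is not the source of the excess of TAATTA, since 1 of 1 hexamers in the top 5% with repeats stayed there without them. Hexamers with CpG filled many of the next ranks, among them GCGCGC (1.83), so matching on GC content leaves a difference in CpG. Whether the excess of TAATTA may reflect bound homeodomain factors was not measured.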
